A study of Mus musculus with 5 samples.

How the data were processed

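RNA was taken from ear skin of control mice (3 samples) and of mice without Cd1d (KO, 2 samples), and total RNA libraries were sequenced. The samples were grouped by their titles, which also give the replicate numbers. The deposited table holds whole-number read counts per gene, not normalized, for 27179 Entrez gene identifiers. Per the submitters' processing notes, the tools behind these deposited counts and their comparison included FastQC, the aligner HISAT2 2.0.4 and DESeq2 1.16.1, with the mouse genome build GRCm38 (mm10). The counting program, the strand setting, and the treatment of reads shared between genes are not given in the sources used here. Ribosomal RNA removal or poly(A) selection is also not given, and either could change the level of small RNA and histone genes.

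From these counts, everything else was computed here. Gene symbols and positions came from the RefSeq annotation of GRCm38 (25275 of 27179 identifiers had a symbol; the rest stayed in library totals). The longest annotated transcript and its GC content were matched from GENCODE for 21572 genes and covered 90.5% of tested genes and 93.9% of genes that passed. Genes with low counts were removed with filterByExpr, which left 17472. Libraries were scaled with TMM factors between 0.936 and 1.07. Differences between KO and control were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.154. CPM values are TMM-normalised. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and adjusted over 40 lists, and tested again with an estimated correlation and with fry. Genes near Cd1d1 were compared with genes elsewhere by a two-sided Fisher's exact test.

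The groups, the tests, the 40 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Cd1d1 and Cd1d2 and, among genes past the threshold with non-overlapping groups and a mean of at least 1 CPM, the 12 largest rises and 12 largest falls, passing over predicted and clone-named genes. It also names up to 4 members of each list with the smallest p. Exceptions are named as chosen later. In all, 10 listed symbols were matched through an older symbol and 2 listed genes, Krt85 and Hbb-bt, were not in the count table used here.

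The alternatives were other scalings (DESeq2 size factors, upper quartile, library size alone), other count filters, robust estimation off, a muscle covariate, the replicate number as a block, DESeq2 1.42.0, limma voom with quality weights, a fold limit, other windows around Cd1d1, and leaving out each replicate. Without a KO replicate, a lone KO library is assumed to vary like the controls. Alternatives added after the data were seen were per-library offsets on transcript length and GC content (smooth trends fitted with mgcv), on length alone, an estimated correlation in the offset fits and for lists gained under an alternative, a ribosomal list without Rps6k genes, and the region test without the epidermal differentiation complex. In random lists matched on length and expression, 10000 draws were used.

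Duplicate libraries were looked for with a chi-square of counts per degree of freedom, which was 24 to 81.1 between libraries of a group, so none differed by sampling noise alone. Whether replicate numbers pair the samples was checked by correlating deviations from the group means of same-numbered libraries. On simulated data with 200 changed genes over 17218 genes, the KO against control test recovered 24% of genes changed 1.5-fold, 70% of 2-fold, 78% of 3-fold and 94% of 4-fold, with 13 false calls among 146. Small changes would therefore often be missed. These simulated data held no length trend. With the same 200 changed genes and a length trend added to the KO libraries, 879 genes passed without offsets. Spearman's rho of fold change with length was then -0.66. With length and GC offsets 143 genes passed, 11 of them false. The 13 false calls therefore do not describe the main fit, where rho was -0.55, and a length trend can add many false calls.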

Results

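RNA sequencing measured gene expression in the ear skin of mice lacking Cd1d, the molecule that presents lipids to natural killer T (NKT) cells, and of control mice. The series addressed how loss of Cd1d alters the transcriptome of the skin. There were 3 control libraries and 2 knockout (KO) libraries. The control titles give the genotype as +/-, while the genotype tag of the same samples says WT, so they are called controls here. The labels do not state that each library came from a separate mouse, and the p-values therefore measure the spread between these 5 libraries. Total counts over 27179 genes were 79160005, 73692964 and 32353957 in control replicates 1, 2 and 3, and 54596686 and 45270805 in KO replicates 1 and 2. A single read was worth 0.0126 to 0.0309 CPM (counts scaled to library size). All 5 libraries expressed the Y-linked genes Ddx3y (2795 to 9389 counts) and Eif2s3y, and Xist had at most 20 counts.

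Cd1d1, the mouse gene for the antigen-presenting molecule CD1d (Entrez 12479, chromosome 3, 86995834 to 87012358 on GRCm38), was lower in both KO libraries than in every control library. Its level was 7.33 ± 2.26 CPM in controls (SD, n = 3) and 1.2 ± 0.05 CPM in KO (SD, n = 2). The log2 fold change was -2.67 with a standard error of 0.29 (edgeR quasi-likelihood test, adjusted p = 0.0152), a level 6.35-fold lower. Raw counts were 557, 757 and 182 in the controls and 61 and 48 in the KO libraries, so reads over the gene remained in KO. Gene totals do not show which exons these reads came from. The neighbouring paralogue Cd1d2 (chromosome 3, 86986586 to 86989533) had 0, 9 and 4 counts in controls and 3 and 1 in KO, too few to test. The genotype labels and the Cd1d1 level pointed the same way in each of the 5 libraries. The adjusted p of Cd1d1 was 0.0935 without control replicate 1 and 0.336 without KO replicate 1, while its log2 fold change stayed at -2.73 and -2.72.

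**Figure D1:**
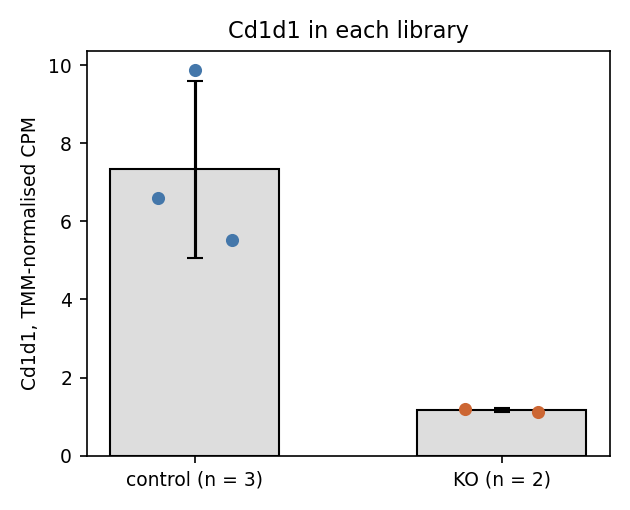
Cd1d1 level (TMM-normalised CPM, linear axis from 0) in control and KO skin, with a point for each library, bars at the group mean and error bars of 1 SD. The KO libraries lie at 1.19 and 1.12 CPM, and the control libraries between 5.52 and 9.87 CPM.

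The largest rises in KO skin included genes of slow and cardiac muscle, small RNAs and ribosomal or mitochondrial genes. Myl2 and Myl3, myosin light chains of slow and cardiac muscle, rose with log2 fold changes of 1.31 (SE 0.14) and 1.29 (SE 0.20). Myl2 went from 6.37 ± 0.39 CPM (SD, n = 3) to 15.8 ± 0.89 CPM (SD, n = 2). Pet100, an assembly factor of cytochrome c oxidase, rose by 1.22 (SE 0.14), and Rpl41, a protein of the large ribosomal subunit, by 1.07 (SE 0.15). The nonagouti gene a, whose product switches melanocytes to yellow pigment, rose by 1.15 (SE 0.23). Ifi27l2a, an interferon-inducible gene, rose by 1.06 (SE 0.18), and the histone gene H4c8 by 1.06 (SE 0.23). Fcor (1.29), Gpha2 (1.27), the let-7 microRNA gene Mirlet7i (1.23), Otos (1.19) and the small nucleolar RNA gene Snord104 (1.15) completed the 12 largest rises.

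The largest falls included genes for signalling, adhesion and gene regulation. The kinase gene Nrk had a log2 fold change of -1.87 (SE 0.34), and Zbed6, a transcriptional repressor, -1.54 (SE 0.17). Cacna1e, a voltage-gated calcium channel subunit, had -1.53 (SE 0.35), and Sdk2, an adhesion molecule of neurons, -1.49 (SE 0.30). Itga2, the collagen-binding integrin alpha 2 subunit, went from 4.25 ± 0.59 CPM to 1.68 ± 0.57 CPM, a log2 fold change of -1.34 (SE 0.27). Mdm4, an inhibitor of p53, went from 21.8 ± 2.47 CPM to 9.26 ± 0.91 CPM, a log2 fold change of -1.24 (SE 0.15). The other falls were of Slfn9 (-1.53), the zinc finger gene Zfp109 (-1.43), the Myb family gene Mybl1 (-1.41), Ppifos (-1.35), Pcdhga10 (-1.26) and the zinc finger gene Plag1 (-1.23). Several values of the rises and falls are uncertain, since the strand setting of the counting is not given in the sources used here. Zbed6 lies inside Zc3h11a. Opposite-strand genes overlap Myl2 (Ccdc63), Gpha2 (Ppp2r5b), Pet100 (Pcp2), Ifi27l2a (Ifi27) and Ppifos (Ppif). The gene a overlaps Gm14226, Slfn9 overlaps 1190001M18Rik and Mir7679, Mdm4 overlaps the pseudogene Gm29257, and Pcdhga10 shares its span with 28 other annotated genes. Rpl41 and H4c8 have near-identical copies, and Mirlet7i lies within the span of D630033A02Rik. Of these 24 genes 16 still passed with length and GC offsets and 4 with length offsets alone (edgeR). Those that did not pass with length and GC offsets were Gpha2, Mirlet7i, Ifi27l2a, H4c8, Cacna1e, Mybl1, Itga2 and Plag1. In that fit Ifi27l2a had a log2 fold change of 0.52 and H4c8 of 0.48. None passed with the muscle covariate or without control replicate 1, where few or no genes did. With a KO replicate left out, and so a single KO library, most or all of the 24 did not pass. With robust estimation off 3 of the 24 did not pass, and 1 each with library size scaling and without control replicate 2.

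Of 17472 genes tested, 657 passed an adjusted p of 0.05, 474 higher and 183 lower in KO (edgeR quasi-likelihood test, Benjamini-Hochberg). The smallest adjusted p was 0.0152, and 3819 genes had an unadjusted p under 0.05. Among the 657, 62 changed by at least 1 on the log2 scale, 23 higher and 39 lower. The control and KO values did not overlap for 39.9% of tested genes, where chance gives 20%. With scaling to library size alone, 268 genes were higher and 974 lower, 446 of these among the 657. The median log2 fold change of all genes was then -0.16. The count rested on single libraries. It was 0 without control replicate 1 (edgeR, 2253 genes at an unadjusted p under 0.05). In each fit without a KO replicate a single KO library remained, and most or all of the 657 genes no longer passed. The count was 1334 without control replicate 2 and 3277 without control replicate 3.

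Transcript length differed between genes that rose and genes that fell. The longest annotated transcript had a median of 1078 bases for genes higher in KO, 7168.5 bases for genes lower in KO and 3271 bases for all tested genes. Across genes, which are not independent replicates, Spearman's rho between the log2 fold change and transcript length was -0.55, and between the log2 fold change and GC content 0.33. Genes of 500 to 1000 bases had a median log2 fold change of 0.46, with 181 of 757 higher and 1 lower. Genes of at least 8000 bases had a median of -0.32, with 71 of 863 lower and 0 higher. Both KO libraries showed the length trend (rho of -0.46 and -0.45 for the deviation from the mean of all libraries, against 0.19 to 0.45 in the controls). The GC trend did not separate the groups, since control replicate 3 (0.43) lay above both KO libraries (0.16 and 0.37). For the lists that passed and for the region near Cd1d1, values are also given with length and GC offsets, an alternative chosen after seeing the data that removes each library's trend on both.

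**Figure D2:**
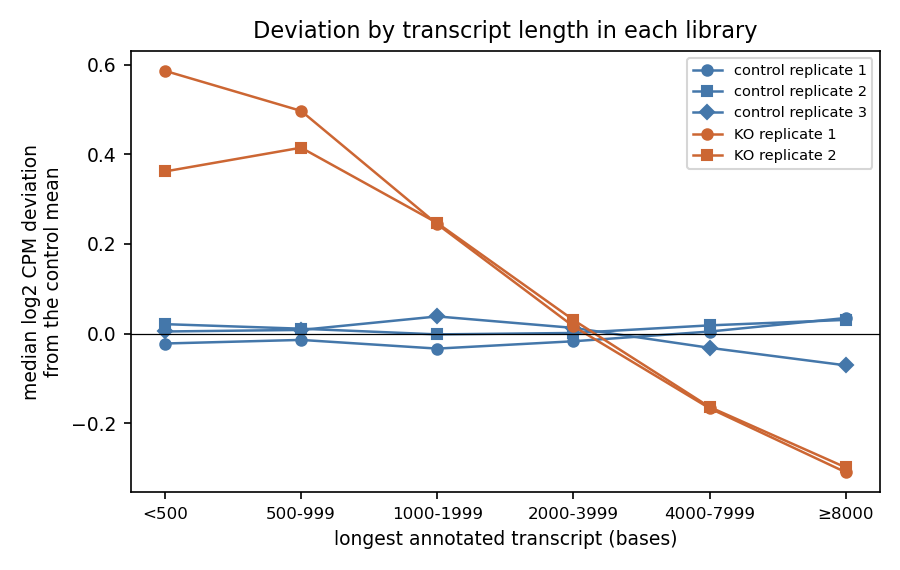
Median log2 CPM deviation from the mean of the controls (vertical axis) by length of the longest annotated transcript in bases (horizontal axis), with a line for each library. In genes of 500 to 1000 bases the KO libraries lie at 0.50 and 0.41 and the controls between -0.01 and 0.01, and in genes of at least 8000 bases the KO libraries lie at -0.31 and -0.30.

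The lists of ribosomal protein genes and of respiratory chain complex I had the smallest p by camera. Of 119 tested genes named Rpl or Rps, 44 rose, 2 fell and 73 did not pass (84 and 2 adjusted over the list alone), with a median log2 fold change of 0.51. Rps14 rose by 0.92 (SE 0.12) and Rplp1 by 0.81 (SE 0.12). Rps3a1 went the other way, from 1112 ± 90.7 CPM to 552 ± 14.5 CPM, a log2 fold change of -1.01 (SE 0.12). This list also holds 10 Rps6k kinase genes, which encode no ribosomal protein, and 1 of these fell. It also holds 19 named pseudogenes. Of 50 complex I genes, 18 rose, 0 fell and 32 did not pass (38 and 0 adjusted over the list alone), with a median of 0.45. Ndufa2 rose by 1.03 (SE 0.12), Ndufa7 by 0.85 (SE 0.11), Ndufb2 by 0.78 (SE 0.12) and Ndufb8 by 0.77 (SE 0.12). Both lists passed camera with a preset correlation of 0.01 (adjusted p = 9.54e-37 and 2.9e-26), but adjusted p = 0.242 with an estimated correlation for each. Their median transcripts had 1114.5 and 1170.5 bases, and with length and GC offsets the medians were 0.22 and 0.18, with 21 and 9 genes higher. Among 10000 random lists matched on transcript length and expression, the median of 102 ribosomal genes with a known length (0.50) lay at the percentile of 100, and that of 46 complex I genes (0.45) at 98.8. Such random lists treat genes as independent and are not matched on GC. Mitochondrially encoded, immediate early and mast cell lists, which did not pass camera in the main fit, also lay near an end (percentiles of 0, 0 and 0.14). With length and GC offsets these lists passed camera as lower (adjusted p = 0.00215, 0.0499 and 0.000837). With an estimated correlation in that fit their adjusted p lay between 0.751 and 0.981. A percentile near an end is not evidence on its own, since the draws treat genes as independent.

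Keratins of the hair shaft and inner root sheath and keratin-associated proteins were high in a single library, KO replicate 1. The 21 tested hair keratin genes had a median deviation from the control mean of 5.14 on the log2 scale in KO replicate 1 and 0.093 in KO replicate 2, while the controls lay at -0.15, -0.53 and 0.89. Krt71, a keratin of the inner root sheath, had 9764 counts in KO replicate 1, 121 in KO replicate 2 and 226, 106 and 148 in the controls. Krt27 had 5562 counts in KO replicate 1 against 108 to 187 elsewhere, and Tchh, the gene for trichohyalin, 8544 against 298 to 735, and these 3 genes were chosen after their values were seen. None of the 21 genes passed, also when adjusted over the list alone. Of 39 keratin-associated protein genes, 1 rose, Krtap19-4, by 2.31 (SE 0.55), and 38 did not pass (3 and 0 adjusted over the list alone). Both lists passed camera (adjusted p = 0.000282 and 9.2e-08), but adjusted p = 0.877 with an estimated correlation for each. Without KO replicate 1 their medians went from 4.16 and 3.36 to -0.05 and 0.004, with an adjusted p of 0.862 for both by camera. Both lists still passed with length and GC offsets, with medians of 3.92 and 2.81, but had adjusted p = 0.981 by camera with an estimated correlation in that fit.

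**Figure D3:**
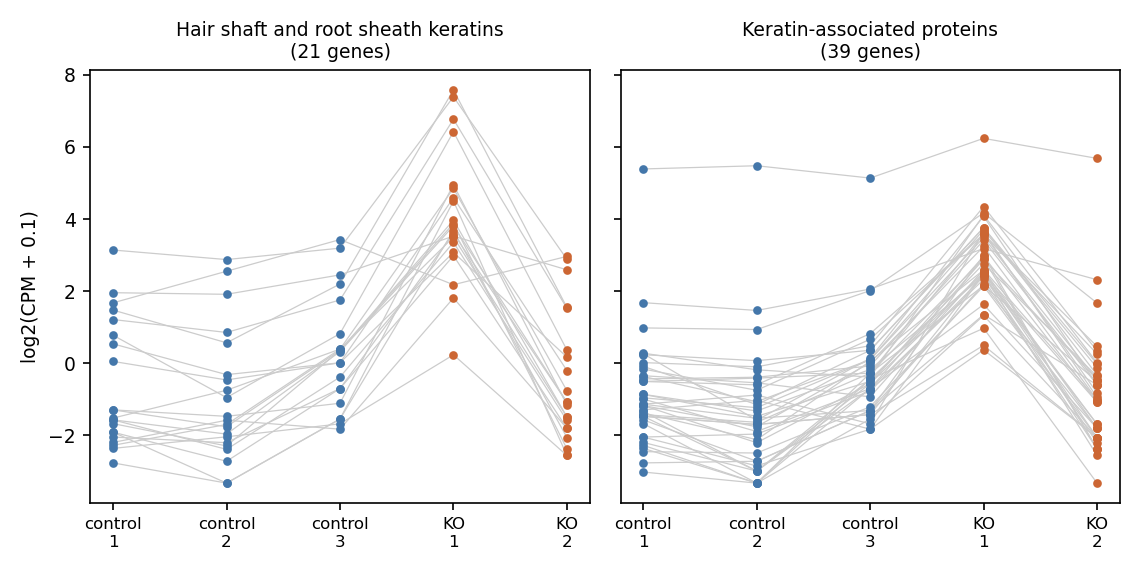
Expression as log2(CPM + 0.1) of hair shaft and inner root sheath keratins (21 genes) and keratin-associated proteins (39 genes) in each library, with a point for each gene and a grey line joining its values. KO replicate 1 stands above the other 4 libraries for most genes, and KO replicate 2 lies among the controls.

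Small parts of the muscle and basal keratinocyte lists passed. Of 20 muscle genes, 4 rose, 1 fell and 15 did not pass (10 and 2 adjusted over the list alone), with a median of 0.36. Pvalb, the calcium buffer parvalbumin, rose by 0.94 (SE 0.15), Tnnc2 by 0.71 (SE 0.12), Tnni2 by 0.69 (SE 0.11) and Mylpf by 0.60 (SE 0.13). The gene that fell, named after its value was seen, was Ttn, for titin (-0.59, SE 0.14). With length and GC offsets 2 muscle genes rose and 0 fell, so Ttn no longer passed as lower. Of 14 basal keratinocyte and basement membrane genes, 3 fell, 0 rose and 11 did not pass (1 higher and 3 lower adjusted over the list alone), with a median of -0.25. Those that fell were Dst, which links keratin to hemidesmosomes (-0.82, SE 0.13), Lama3, a chain of laminin 332 (-0.78, SE 0.12), and Itga6, the hemidesmosome integrin (-0.78, SE 0.14). The camera calls (adjusted p = 5.34e-05 and 0.00417) were lost, with adjusted p = 0.856 for muscle and 0.877 for basal keratinocytes with an estimated correlation. With length and GC offsets the medians were 0.14 and -0.12 and both lists still passed, but with length offsets alone the basal keratinocyte median was -0.065 and its list did not pass camera on the edgeR fit (adjusted p = 0.0894). The muscle deviation in the fit with both offsets came from KO replicate 2 (0.25), while KO replicate 1 (0.028) lay within the controls (-0.053 to 0.041). Camera with an estimated correlation and length and GC offsets gave adjusted p = 0.981 for muscle and 0.775 for basal keratinocytes. Without KO replicate 1 the basal keratinocyte list had an adjusted p of 0.115 by camera.

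Among genes of the cornified layer, 4 of 36 epidermal differentiation genes rose, 0 fell and 32 did not pass (12 higher and 4 lower adjusted over the list alone). These were the late cornified envelope genes Lce1b (0.87, SE 0.13), Lce1a1 (0.70, SE 0.12), Lce1d (0.67, SE 0.12) and Lce1c (0.55, SE 0.12), a family of similar genes whose reads the counting could have split. The list median was 0.17, and the camera call (adjusted p = 0.0176) had adjusted p = 0.589 with an estimated correlation. With length and GC offsets the median was 0.05, none of its genes passed and the list did not pass camera (adjusted p = 0.556). Of 15 adipocyte genes 1 rose, Cfd, the gene for adipsin (0.71, SE 0.15), and 14 did not pass (4 and 0 adjusted over the list alone). The adipocyte median was 0.19, with adjusted p = 0.0291 by camera and adjusted p = 0.877 with an estimated correlation, and 0.0931 with length and GC offsets. Of the sex check genes 1 of 4 fell, the Y-linked demethylase gene Kdm5d (-0.71, SE 0.16), and 3 did not pass (0 and 2 adjusted over the list alone). Its list had adjusted p = 0.0282 by camera, adjusted p = 0.877 with an estimated correlation, and 0.339 with length and GC offsets, where no gene of the list passed. The epidermal list had an adjusted p of 0.131 without KO replicate 1, 0.0512 without KO replicate 2 and 0.0755 with library size scaling by camera on the edgeR fit. The adipocyte list had 0.257 without KO replicate 1, 0.0523 without control replicate 1 and 0.25 without control replicate 3. The sex check list had 0.243 without KO replicate 2 and 0.0745 without control replicate 2.

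NKT cells depend on Cd1d, and the transcripts that mark them were barely covered. Trav11, Trav11d and Traj18, the segments of the invariant receptor, had 0 counts in all 5 libraries. If reads of the receptor are counted on these segments, this allows at most 0.0356 to 0.091 CPM in a library (3 counts). The treatment of reads shared between genes is not given, so that limit is uncertain. Of 12 marker genes 5 could be tested, and 0 passed, also when adjusted over the list alone (edgeR, adjusted p between 0.21 and 0.947). Their log2 fold changes were -0.51 for Zbtb16 (SE 0.22), 0.63 for Tbx21 (SE 0.42), 0.71 for Klrb1c (SE 0.62), 0.09 for Cxcr6 (SE 0.28) and 0.04 for Il2rb (SE 0.22). Without control replicate 2 Zbtb16 passed as lower (-0.69, SE 0.18, edgeR adjusted p = 0.0284), and with each other replicate left out none of these genes passed. Zbtb16 is also expressed outside lymphocytes. A change in NKT cells was not detectable at this depth. Among 16 T cell genes 0 passed over all genes, and Trac and Trbc1 and Trbc2 passed adjusted over the list alone. Trac, the constant region of the alpha receptor chain, went from 0.489 ± 0.13 CPM to 0.117 ± 0.001 CPM (log2 fold change -2.05, SE 0.55, edgeR adjusted p = 0.0661 over all genes), while Trbc1 (0.70, SE 0.19) and Trbc2 (0.44, SE 0.13) of the beta chain had positive values. No NKT cell, T cell, gamma-delta T cell, NK cell, B cell, macrophage, dendritic cell, neutrophil or mast cell list passed camera (adjusted p between 0.224 and 0.979). The mast cell list passed as lower with length and GC offsets, with a median of -0.28 (camera on the edgeR fit, adjusted p = 0.000837, and 0.751 with an estimated correlation). Without KO replicate 2 the NK cell list passed as higher, with a median of 0.60 against 0.38 (camera on the edgeR fit, adjusted p = 0.0451, and 0.697 with an estimated correlation).

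A few genes of antigen presentation and host defence rose. Of 12 MHC class II genes 1 rose, H2-Ab1 (0.49, SE 0.12), and 11 did not pass (3 and 0 adjusted over the list alone), with a median of 0.32. Of 17 antimicrobial genes 1 rose, Wfdc21 (0.77, SE 0.13), and 16 did not pass (3 and 0 adjusted over the list alone), with a median of 0.25. Both lists passed camera (adjusted p = 0.00543 and 0.0109) and had adjusted p = 0.877 with an estimated correlation. Neither passed camera on the edgeR fit with length and GC offsets (adjusted p = 0.57 and 0.748), and the antimicrobial median was -0.036. None of the antimicrobial genes passed in that fit. Without KO replicate 1 neither passed camera on the edgeR fit (adjusted p = 0.137 for both), and the antimicrobial list had an adjusted p of 0.123 without control replicate 3. The MHC class I list did not pass camera on the edgeR fit (adjusted p = 0.0766), although its immunoproteasome genes Psmb10 (0.65, SE 0.12) and Psmb9 (0.55, SE 0.13) rose. By fry this list passed (adjusted p = 0.0234), 1 of 3 lists that did, but it had adjusted p = 0.856 by camera with an estimated correlation and 0.556 with length and GC offsets. In the fit with offsets 1 MHC class I gene passed as higher and 1 as lower, so Psmb10 and Psmb9 did not both pass as higher. In the interferon list, Bst2 (tetherin) rose by 0.57 (SE 0.12), Ifit2 had -0.93 (SE 0.22) and fell, and 22 of 24 genes did not pass (adjusted p of the list = 0.985). With length and GC offsets no gene of this list passed as higher. Inflammatory cytokines, type 2 immunity and keratinocyte activation did not pass camera on the edgeR fit (adjusted p = 0.985, 0.232 and 0.874). With length offsets alone the cytokine and keratinocyte activation lists passed camera as lower (adjusted p = 0.0115 and 0.0222), but both had 0.894 with an estimated correlation.

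**Figure D4:**
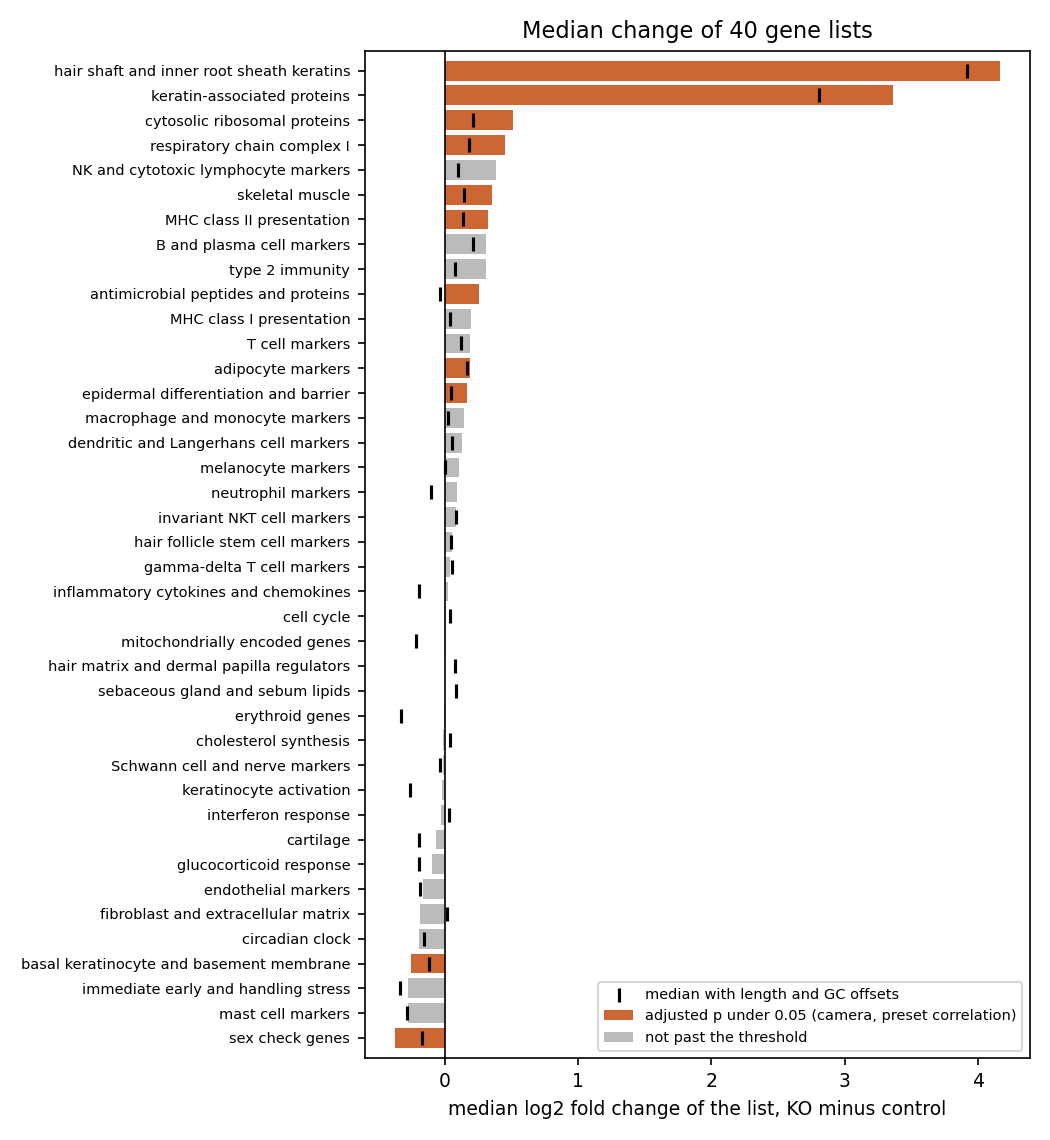
Median log2 fold change (KO minus control) of each of 40 gene lists, in orange where the list passed camera with a preset correlation and in grey where it did not, with a black mark at the median with length and GC offsets. The hair keratin list (4.16) and keratin-associated proteins (3.36), both from KO replicate 1, lie far above the ribosomal (0.51) and complex I (0.45) lists.

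Genes near Cd1d1 on chromosome 3 passed more often than genes elsewhere. Within 10 Mb of Cd1d1, 34 of 304 tested genes passed (11.2%), against 613 of 16615 elsewhere (3.69%), an odds ratio of 3.29 with a 95% confidence interval of 2.21 to 4.76 (two-sided Fisher's exact test over genes, p = 2.14e-08). Genes are not independent replicates in this test. The window holds the epidermal differentiation complex, a cluster of skin barrier genes, taken here as S100a1 to S100a10 (90511034 to 93564645). Of 57 tested genes in it 18 rose, among them S100a14 (0.56, SE 0.11), S100a4 (0.64, SE 0.11) and Lce1b. Only 1 of the 57 passed with length and GC offsets, S100a14 (0.36, SE 0.09), while S100a4 had 0.16 (SE 0.10), and the median of the 57 went from 0.53 to 0.069. Outside it 9 genes rose, among them Tsacc (1.05, SE 0.17), Bola1 (0.85, SE 0.11) and Dpm3 (0.83, SE 0.13), and 7 fell. Rps3a1 (86137940 to 86142668), Gucy1b1, a subunit of the nitric oxide receptor (-0.85, SE 0.16), the interleukin-6 receptor gene Il6ra (-0.69, SE 0.13) and Tpm3, a tropomyosin (-0.50, SE 0.11), were among those that fell. With length and GC offsets Tsacc (0.56) and Bola1 (0.41) passed and Dpm3 (0.38) did not (edgeR). Rps3a1 (-1.34), Gucy1b1 (-0.76), Il6ra (-0.41) and Tpm3 (-0.57) passed there as lower. Other genes, among them Glmp (0.40) and Rit1 (0.40), passed only with the offsets. The odds ratios with and without offsets thus rest on partly different genes. All these genes were chosen after their values were seen. With length and GC offsets the odds ratio was 1.5 (0.82 to 2.53, Fisher's exact test, p = 0.146), and without the epidermal differentiation complex it was 1.81 (1.01 to 3.02, p = 0.0394).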

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

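Chosen after the data were seen were the length and GC offsets (also with an estimated correlation), the length offsets, the list without Rps6k genes and the region test without the epidermal differentiation complex. The 657 changed genes became 1242 with library size scaling (268 higher, 974 lower, 446 of the 657 shared) and 1036 without a count filter. They became 1772 with DESeq2, 4662 with limma voom and 62 with a fold limit. The count was 10 with the muscle covariate (which shared 0 of the 657 and separates the groups). It was 588 with length and GC offsets (240 shared) and 22 with length offsets (21 shared). DESeq2 size factors (684), upper quartile (693), the stricter filter (770) and robust off (657) gave counts within 1.5 times. Leaving out each replicate gave 0 to 3277 genes. It was 0 without control replicate 1 (edgeR, 2253 at an unadjusted p under 0.05). Between 647 and 657 of the genes kept their sign under each alternative. All 657 were selected in these same data and had non-overlapping groups, so a kept sign was nearly given in advance and is no separate support. Cd1d1 kept a negative log2 fold change under every alternative, -2.83 to -2.39 over left-out replicates, and did not pass with the muscle covariate (-1.74, adjusted p = 0.692), without control replicate 1 (0.0935) or without KO replicate 1 (0.336). The 11 lists that passed became 0 with an estimated correlation, also with length and GC offsets, and 3 by fry (ribosomal, complex I and MHC class I, the last not among the 11), and 5 to 14 lists passed with a replicate left out. The antimicrobial list median turned to -0.036 with length and GC offsets and -0.14 with length offsets. The odds ratio near Cd1d1 was 1.5 with length and GC offsets and 1.73 with these and without the differentiation complex (Fisher's exact test, p = 0.146 and 0.0512), and 1.62 to 4.32 over left-out replicates. It had no value without control replicate 1 or KO replicate 1, where fewer than 10 genes passed. The cause of these changes was not tested. At this depth a change was not detectable in the untested NKT genes, at 0 to 10 counts a library.

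With the replicate number as a replicate block, 2037 genes and 7 lists passed. Number 3 occurs only among the controls, so the KO contrast of that fit rests on the 2 same-numbered pairs. The log2 fold change of Cd1d1 was -2.79 in it, near the -2.83 without control replicate 3. The deviations of same-numbered libraries had correlations of 0.02 and 0.06 over 2 pairs, so the numbers are not taken to pair the samples.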

Other observations

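The tests of the chance splits, of the hair genes in KO replicate 2, of the epidermal differentiation complex, of the length trend in the ribosomal lists and of RNA quality were chosen only after the result was seen. Among lists outside the report, fibroblast and matrix genes gave 1 fall of 19, Lox, which cross-links collagen (-0.63, SE 0.15), and endothelial genes 1 rise of 13, Cldn5 (0.53, SE 0.12). In the endothelial list 5 genes were lower adjusted over the list alone and not over all genes, among them the lymphatic genes Lyve1 (-0.53) and Prox1 (-0.95) and Cdh5 (-0.48). Over all genes 5 endothelial genes were lower without control replicate 3 and 2 with length and GC offsets. Cartilage gave Cytl1 (0.57, SE 0.12), sebaceous genes Awat2, a wax synthase (0.65, SE 0.14), glucocorticoid response genes the metallothionein gene Mt1 (0.52, SE 0.11) and cytokines Ccl27a, a skin chemokine (0.65, SE 0.15). With length and GC offsets no gene of the fibroblast, cartilage, glucocorticoid or cytokine lists passed over all genes. The fibroblast, endothelial, cartilage, sebaceous, circadian, cell cycle, cholesterol, Schwann cell, melanocyte, erythroid, hair follicle stem cell, hair matrix, mitochondrially encoded, immediate early and glucocorticoid lists did not pass camera (adjusted p between 0.128 and 0.979). With length and GC offsets the mast cell and mitochondrially encoded lists passed camera as lower (medians -0.28 and -0.21), but both had adjusted p = 0.751 with an estimated correlation. The immediate early list also passed there (adjusted p = 0.0499, and 0.981 with an estimated correlation), but both KO libraries (-0.29 and -0.26) lay within the controls (-0.32 to 0.50, the highest in control replicate 3). Other lists passed camera in single alternatives: fibroblast as lower with library size scaling (adjusted p = 0.0337) and without control replicate 1 (0.0164), circadian as lower without KO replicate 1 (0.00416) and control replicate 2 (0.0352), and without control replicate 2 erythroid as higher (0.0181), mitochondrially encoded as higher (0.0352) and immediate early as lower (0.0467). With an estimated correlation in the same fits these had adjusted p between 0.661 and 0.95.

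The real grouping gave 657 genes, and the highest of the other splits into 3 and 2 gave 3. With 10 splits, of which 1 gave as many, a share under 0.05 cannot be reached.

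Short transcripts were higher and long transcripts lower in KO. A trend from a single library is argued against, because rho with length was -0.47 in the leave-one-out fit nearest 0. Depth as the whole cause is argued against, because the library with the lowest total had a rho of 0.19, on the side of the other controls. Within the controls rho fell with the total count (0.449, 0.305 and 0.192 in control replicates 1, 2 and 3), so a part from depth is not excluded. Whether length and GC trends were the whole cause of the ribosomal and complex I rises is not settled. With offsets the medians were 0.22 and 0.18, and for both lists both KO libraries lay above every control. Both lists passed camera with the preset correlation in that fit. With an estimated correlation neither passed (with offsets adjusted p = 0.14 for ribosomal and 0.751 for complex I genes). Whether length or GC dependent recovery made the trend over all genes stays open, although both limits set beforehand to exclude it were met. The 588 genes that passed with offsets held only 240 of the 657, and length offsets alone left 22. The percentiles of 100 and 98.8 among matched random lists concern only 102 ribosomal and 46 complex I genes, in draws that treat genes as independent. Both limits were therefore wrongly chosen for the trend. A difference in RNA quality or library preparation cannot be told apart from genotype, since both KO libraries deviate, the nearer one by 0.41 in genes of 500 to 1000 bases.

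Hair keratins and keratin-associated proteins were high in KO replicate 1. An effect of genotype in both KO libraries is argued against by the median deviation of 0.093 in KO replicate 2, below the highest control, and length dependent recovery by the 4.89 that remained in KO replicate 1 with offsets. In the hair matrix list 13 of 25 tested genes had a positive log2 fold change and 12 a negative one. Among its genes Shh (138 counts against 3 to 14), Padi3 (533 against 6 to 34) and S100a3 (2652 against 328 to 684) were also high in KO replicate 1. These 3 genes were picked after their values were seen. Growing hair follicles in that piece of skin may be the source. The planned test did not bear this out, as the melanocyte median in KO replicate 1 was 0.060, within the range of the other libraries, as was the hair matrix median of 0.14, though without KO replicate 2 the hair matrix list passed as higher (camera on the edgeR fit with a single KO library, adjusted p = 3.19e-05, and 0.752 with an estimated correlation, 3 genes higher). That limit was set aside because the melanocyte list has a median of 19.4 CPM and the matrix list 9.82 CPM in controls, against 0.516 CPM for hair keratins, so a small share of growing follicles could stay hidden, and the question stays open.

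Genes near Cd1d1 passed more often than genes elsewhere. The epidermal differentiation complex held 18 of the 34, of which 1 passed with length and GC offsets. Without the complex the odds ratio was 1.81 (Fisher's exact test, p = 0.0394), and with offsets 1.73 (p = 0.0512). These values lie on both sides of the threshold, and the test treats neighbouring genes as independent. Whether the complex is the whole source therefore stays open. Flanking DNA of another strain, carried along with the knockout, is a candidate explanation, but the odds ratio with length and GC offsets was 1.5 (p = 0.146 by Fisher's exact test), above 1 and not past the threshold. With these offsets the 5 Mb window gave 2.48 (Fisher's exact test, p = 0.00554) and the 20 Mb window 1.67 (p = 0.0258). The strain of the knockout cells is not given in the sources used here, and reads that would show strain variants were not used here.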
